A study of Drosophila melanogaster with 6 samples.

How the data were processed

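Ovary RNA of 6 libraries, 3 wild type and 3 GCNA null, was analysed from a single table of 13216 rows and 6 columns. Per the labels' protocols, total RNA was extracted with a kit that keeps RNA from 18 nt, treated with DNase, depleted of ribosomal RNA, made into strand-specific libraries and sequenced on an Illumina HiSeq instrument. Per the submitters' processing notes, CASAVA 1.8.2, STAR 2.5, DESeq2 and the dm6 assembly were used. The gene annotation, the repeat annotation, the read counter and its strand setting are not given in the sources used here. The deposited values are of the unit signal: counts of reads per gene or repeat divided by 1 size factor per library, as the values themselves show. In each column all values are whole multiples of 1 step, so that whole reads could be recovered for 100% of the values in every library (within 1e-06 of a whole number). The step was 0.935, 1.06 and 1.09 in wild type replicates 1 to 3 and 1.15, 0.789 and 1.01 in GCNA null replicates 1 to 3. The recovered totals were 38401723 to 55758180 reads, so 1 read is worth about 1 normalized count. Over rows under 1000 reads the median chi-square per row was 1.18 to 1.34 between wild type libraries, against 0.455 expected from counting alone, so counting error is a sizeable part of the spread of such rows. Over all rows the median was 2.82 to 3.72.

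Groups were taken from the sample titles and descriptions. Gene rows were matched to the Ensembl BDGP6 annotation, the same assembly as dm6, by symbol or synonym: 12818 of 13000 (98.6%), of which 10117 by the exact symbol. Rows with no match, and repeat rows, have no coordinates here. The table held 70 groups of rows with identical reads and at least 60 reads, such as copies of the core histone genes, which count as 1 measurement each.

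Before any test, libraries were compared by a chi-square test of their reads over rows. For GCNA null replicates 1 and 2 it was 1.66 per degree of freedom, and 1.09 over the 3471 rows under 1000 reads. The chi-square p over those rows was 5.9e-05. The other 5 pairs within a group gave 6.77 to 9.46 on such rows. The 2 libraries thus differed slightly more than sampling alone gives, but far less than any other pair within a group. Their mean was used as 1 sample. The comparison had been planned with 6 separate samples, and the totals and gene list counts under that plan are printed wherever they differ. Merging was thus the departure from the plan, chosen after the data were seen, from the replicate check and before the numbers of changed genes were compared.

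The test was limma 3.58.1 (R 4.3.3; empirical Bayes with a mean-variance trend) on log2 of the normalized count plus 1, GCNA null minus wild type, with no block, over rows with at least 10 normalized counts in at least 3 of the 6 libraries (10132 rows). Differences are on that scale, which understates the change of scarce RNAs. Rows with a two-sided Benjamini-Hochberg adjusted p under 0.05 are called higher or lower. Where a group had no read, the fold is a lower bound against 3 reads over the group. With 1 to 3 reads the ratio of reads is given with its exact 95% interval. Floors and intervals cover counting error only.

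Before the data were examined, a rule for the genes named was fixed: Gcna; the 12 highest and 12 lowest differences among rows past the test with separate groups and a mean of at least 50; up to 4 changed members of each gene list, or the 2 most abundant where none changed; up to 6 changed genes within 1 Mb of Gcna; and the 3 smallest adjusted p among rows with a mean of at least 1000. It named 106 rows, of which 88 passed. Others are said to be chosen after their values were seen. The gene lists were fixed at the same time: DNA-protein crosslinks, DNA damage, meiosis, replication, mitosis, the piRNA pathway, chorion, vitelline membrane and yolk, follicle cells, early germline, oocyte, apoptosis and autophagy, heat shock, immunity, xenobiotic metabolism, ecdysone, histones, markers of muscle, fat body, hemocytes, gut, oviduct, testis and nervous system, and classes of RNA by name. Each list of at least 5 tested members was tested with camera (correlation 0.01), and again with an estimated correlation and with fry, adjusted over the lists. With the estimated correlation the smallest adjusted p was 0.936, and with fry's test for a common direction 0.392, so no list call held with either. The share of changed genes near Gcna was compared by Fisher's exact test.

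Alternatives were other pseudocounts and filters, TMM and quantile scaling, robust empirical Bayes, a replicate block, each library left out in turn, other windows around Gcna, and tests on the recovered reads: edgeR 4.0.16 (quasi-likelihood), which called 653 rows, DESeq2 1.42.0, which called 1297, and limma-voom, which called 721, against 645 with limma. The fits with 6 separate samples, with and without the block, are those planned. They became alternatives when the 2 libraries were merged. The omission of GCNA null replicates 1 and 2 together and the counts of transposable element rows were added after the data were seen.

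The tests were run on simulated counts made for this comparison, with 50 rows changed at each size and 10101 rows tested. limma recovered 25 of 50 rows at 1.5-fold, 26 at 2-fold, 43 at 4-fold and 50 at 8-fold, with 16 false among 160 calls. edgeR had 19 false among 164 calls and DESeq2 56 among 210. In camera none of 20 random lists passed. The simulated rows varied independently of each other, so this check cannot speak for lists whose members vary together. In the data the estimated correlation was 0.35 for transposable elements and 0.48 for mitochondrial ribosomal proteins. It was 0.64 for vitelline membrane and yolk and 0.04 for xenobiotic metabolism. The observed false share of limma on these counts, 16 of 160, was above the nominal 5 percent, and limma missed 7 of 50 rows changed 4-fold, so a row that did not pass may still have changed.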

Results

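Total RNA was sequenced from ovaries of Drosophila melanogaster females aged 1 to 3 days. The wild type was the white-eyed stock wBerlin (3 libraries). The other group carried a null allele of Gcna (3 libraries, called GCNA null), which had been outcrossed to wBerlin for 10 generations. Gcna encodes a germ cell nuclear protein whose relatives act on proteins crosslinked to DNA. Females were collected at 0 to 2 days and fed wet yeast for 24 hours at 25 °C before dissection. The libraries were stranded and depleted of ribosomal RNA, and the extraction kit kept RNA from 18 nt upwards. Rows of small nucleolar RNAs, other non-coding RNAs and repeats were measured beside the messenger RNAs. The 13216 rows of the table comprised 13000 genes and 216 repeats, and the values were read counts normalized for library size. The reads counted per library were 47726399, 44275289 and 41799533 in wild type replicates 1 to 3, and 38401723, 55758180 and 45743278 in GCNA null replicates 1 to 3. The single comparison, GCNA null against wild-type ovaries, asks which RNAs differ in level between the 2 stocks. Any founder chromosome left after the outcrossing differs along with Gcna, so a change is not by itself an effect of its loss.

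GCNA null replicates 1 and 2 differed by little more than the sampling noise of their reads and were counted as 1 sample, the mean of both. Their chi-square per degree of freedom was 1.66 over 10258 rows, whereas the other 5 pairs within a group lay between 26.9 and 100.4. Means ± SD below are therefore over 3 wild type samples and 2 GCNA null samples. The comparison had been planned with 6 separate samples, and a gene group's count under that plan is given wherever it differs. Neither the labels nor the values say that the samples of a group came from separate sets of flies, so p-values measure only the spread between these samples, which may be technical.

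Gcna, listed in the table as CG14814, lies on the X chromosome at 1862009 to 1865835 (BDGP6, the dm6 assembly), on the minus strand. The annotation gives it as a protein-coding gene of 3827 bp, and no other annotated gene overlaps it. CG14814 had 20676, 18292 and 19581 normalized counts in the wild type libraries and 493, 428 and 520 in the GCNA null libraries. Its mean was 19516 ± 1193 in wild type and 490.5 ± 42.3 in GCNA null ovaries, a log2 difference of -5.31 (SE 0.08, limma adjusted p = 2.0e-06). The GCNA null libraries thus kept 2.19% to 2.67% of the mean wild type level of CG14814, and the labels of all 6 libraries fit the level of the targeted gene. Which part of the gene these remaining reads cover was not analysed here.

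Of 10132 rows tested, 431 were higher and 214 were lower in GCNA null ovaries (limma, Benjamini-Hochberg adjusted). At least a 2-fold change was seen in 255 of the higher and 65 of the lower rows, and at least an 8-fold change in 74 and 5. The median log2 difference over all tested rows was -0.00045. In all 645 changed rows the values of the 3 wild type libraries did not overlap those of the 3 GCNA null libraries. The same separation was seen in 38.9% of all tested rows. Chance gives it in 10% of rows for 3 independent libraries against 3, and in more where a pair of them is nearly alike, as here. The first principal component held 61.8% of the variance and separated the groups. The count rested on the small number of samples. With all 6 libraries taken as separate samples it was 935 higher and 749 lower, and DESeq2 on the recovered reads gave 755 and 542. It fell to 270 higher and 98 lower without wild type replicate 1, to 260 and 95 without replicate 2, to 222 and 67 without replicate 3, and to 94 and 52 without the sample of GCNA null replicates 1 and 2. This last setting, and the one without GCNA null replicate 3, keep 1 GCNA null sample, which is assumed to vary like the wild type samples that supply the spread.

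**Figure D1:**
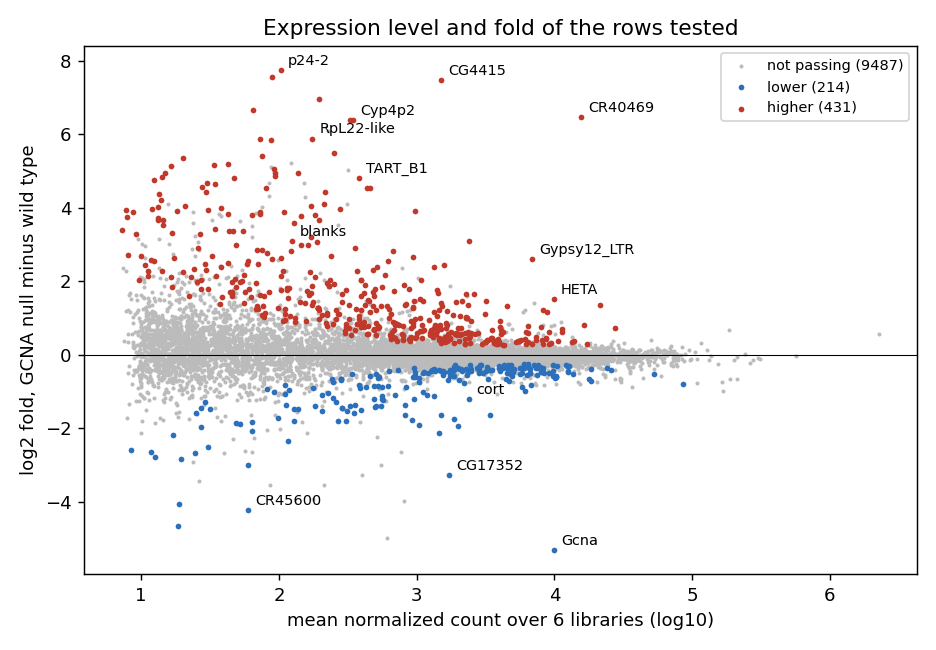
Mean level (log10 of the mean normalized count over the 6 libraries, x axis) against the log2 difference GCNA null minus wild type (y axis), one point per tested row (10132). Coloured points are the 431 higher and 214 lower rows. Gcna lies at -5.31, the lowest value of the tested rows, and most of the large differences are increases of RNAs that were scarce in wild type.

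Most of the 12 largest increases were in RNAs with few or no reads in wild-type ovaries. p24-2, a member of the p24 family of vesicle cargo receptors, had no read in any wild type library and 163, 209 and 248 normalized counts in the GCNA null libraries, at least 212-fold higher against a floor of 3 reads over the group. CG12057 likewise went from 0 in every wild type library to 125, 119 and 290, at least 201-fold higher. CG18853 had 1 read in all wild type libraries together and 402 reads in the GCNA null libraries, a read ratio of 377 (95% interval 67.2 to 14912, counting error only). CG4415, whose current symbol gNacalpha marks a germline subunit of the nascent polypeptide-associated complex, rose from 17.6 ± 7.16 to 3300.4 ± 1365 normalized counts (log2 difference 7.47, SE 0.39, limma adjusted p = 0.00043). The non-coding RNA CR40469, near the tip of the X chromosome at 122493 to 122706, rose from 364 ± 74.2 to 32024 ± 4562 (log2 difference 6.47, SE 0.17, limma adjusted p = 3.8e-05) and had 1067 reads in the 3 wild type libraries together. The cytochrome P450 gene Cyp4p2 rose from 7.68 ± 3.13 to 702 ± 79.2 (log2 difference 6.39, SE 0.34). RpL22-like, a paralog of the ribosomal protein gene RpL22 known for its expression in testis, rose from 5.10 ± 0.756 to 358 ± 64.1 (log2 difference 5.88, SE 0.29, limma adjusted p = 0.00036). The log2 differences of snoRNA:Psi18S-1377b, CG12592, CR43614, Ada1-1 and CG14692 were 6.95, 6.40, 5.88, 5.85 and 5.49.

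The decreases were smaller, and Gcna aside only 4 rows fell at least 8-fold. CG17352 (current symbol Culd) fell from 3096 ± 213 to 323 ± 54.4 normalized counts (log2 difference -3.27, SE 0.12, limma adjusted p = 0.00012). The antisense RNA CR45600 fell from 113 ± 23.5 to 5.51 ± 3.52 (log2 difference -4.22, SE 0.41). The log2 differences were -2.99 for CG33655, -2.33 for PPO3, a prophenoloxidase gene, -2.12 for UBL3, -2.07 for CG3690, -1.94 for pst, -1.91 for nAChRalpha4, a nicotinic acetylcholine receptor subunit, -1.87 for CG32783, -1.83 for Osi2, -1.80 for CR43144 and -1.79 for CG4398. Reads of overlapping genes could be split or shared by the counting, whose strand setting is not given in the sources used here. This makes the values of CR45600, CR43614, CG33655, p24-2, CG4415, CG18853, Cyp4p2 and Ada1-1, which overlap other genes, uncertain, as are those of snoRNAs inside host genes. Of the 87 named rows besides Gcna that passed, 77 passed under every other setting that kept all libraries, and none changed sign under any setting. Without the sample of GCNA null replicates 1 and 2, 51 of the 87 no longer passed.

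**Figure D2:**
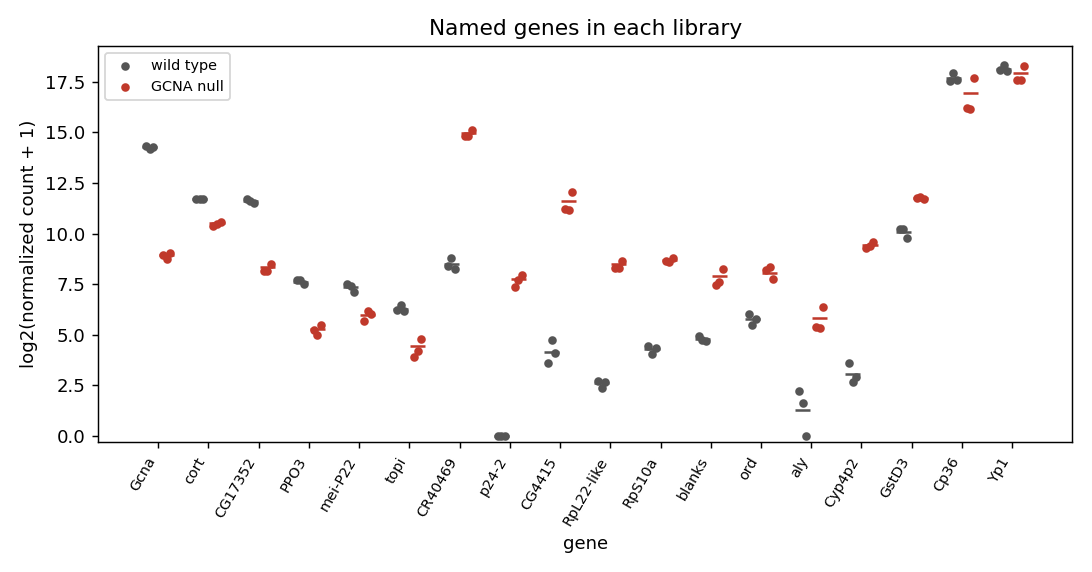
Level (log2 of the normalized count plus 1) of 18 genes in each library, wild type in grey and GCNA null in red; the bar is the mean of the samples counted. CG14814 (Gcna) and CG17352 are lower in every GCNA null library, and CG4415, CR40469 and RpL22-like are higher in every one.

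Genes that respond to DNA damage or act on crosslinked DNA, the pathway in which Gcna relatives work, mostly did not pass the test. Of 11 topoisomerases and crosslink repair genes, 1 fell and none rose, both over all rows and adjusted over the list alone: Top3alpha, a topoisomerase, went from 3161 ± 71.1 to 2606 ± 44.6 (log2 difference -0.28, limma adjusted p = 0.034). In this list 10 of 11 members had a negative log2 difference (median -0.12, and -0.067 without GCNA null replicates 1 and 2). Its camera adjusted p was 0.071, 0.038 with 6 separate samples, and 0.936 with an estimated correlation on 5 samples. Of 26 checkpoint, p53 and damage response genes, Corp alone passed (log2 difference -0.43, limma adjusted p = 0.015), also within the list alone (1 higher and 3 lower with 6 separate samples, 3 lower with DESeq2). The median log2 difference of the list was -0.0087. Corp is a p53 target.

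Meiosis and cell cycle genes showed single changes. Among 28 genes of meiotic recombination, 1 rose and 1 fell, also adjusted over the list alone (3 and 1 with 6 separate samples, 2 and 1 with DESeq2). ord, needed for cohesion of sister chromatids in meiosis, rose from 54.2 ± 9.60 to 266 ± 66.7 normalized counts (log2 difference 2.26, SE 0.25, limma adjusted p = 0.0055), and mei-P22, needed for meiotic double-strand breaks, fell from 162 ± 21.2 to 62.4 ± 2.83 (log2 difference -1.35, SE 0.19, limma adjusted p = 0.013). Of 39 DNA replication genes, DNApol-alpha50 (primase) rose by 0.42 and Psf1, of the GINS complex, fell by 0.60 on the log2 scale, the same 2 when adjusted over the list alone. Of 33 mitotic genes 1 fell, also adjusted over the list alone: cort, a female-specific activator of the anaphase-promoting complex in meiosis, went from 3352 ± 37.1 to 1463 ± 115 (log2 difference -1.20, SE 0.07, limma adjusted p = 0.0005). The median log2 differences of these 3 lists were -0.034, -0.00052 and -0.021. Among 10 histone variant and histone processing genes none passed with limma, edgeR, limma-voom or DESeq2 on 5 samples, over all rows or adjusted over the list alone, 1 had an unadjusted p under 0.05, and 1 was lower with 6 separate samples. His3.3B and His2Av had log2 differences of 0.04 and 0.01 (list median -0.018). Of 66 core histone rows, 5 passed, all as higher and also adjusted over the list alone, but these were 5 copies of His4 with the same reads (His4:CG33891 and 4 others, log2 difference 1.27) and amount to 1 measurement. With 6 separate samples, and with DESeq2, 7 rows were higher. The median of the core histone rows was -0.03, -0.19 without GCNA null replicates 1 and 2, 0.084 without replicate 3 and -0.22 with quantile normalization, over rows that include copies with identical reads.

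Of 195 transposable element rows tested, 30 were higher and 1 lower (46 and 4 adjusted over the list alone). The median log2 difference was 0.22, and 151 rows had a positive one; the median was 0.22 with TMM scaling and 0.079 with quantile normalization. The camera test with a preset correlation between rows gave an adjusted p of 9.4e-07 for a shift upwards relative to other rows; the adjusted p was 0.936 with an estimated correlation. By class, 21 of 130 LTR rows, 7 of 37 LINE rows and 2 of 27 DNA transposon rows were higher, and the lower row was the LTR element HMSBEAGLE_I-int:Gypsy:LTR (log2 difference -0.57). The LTR and internal part of 1 element are separate rows. Grouped by name into 137 families, 25 had a higher row and 1 a lower row. At least a 2-fold increase was seen in 21 rows. The 3 families that maintain Drosophila telomeres were among them. HETA:Jockey:LINE rose from 5209 ± 222 to 14854 ± 1267 normalized counts (log2 difference 1.51, SE 0.07, limma adjusted p = 0.00036) and TART_B1:Jockey:LINE from 24.1 ± 4.05 to 707 ± 133 (log2 difference 4.82, SE 0.23), while TAHRE:Jockey:LINE and TART:Jockey:LINE had log2 differences of 1.47 and 1.04. Gypsy12_LTR:Gypsy:LTR rose from 1916 ± 144 to 11595 ± 849 (log2 difference 2.60, SE 0.08, limma adjusted p = 8.7e-05), and its internal part, Gypsy12_I-int:Gypsy:LTR, had a log2 difference of 1.69. TAHRE, TART, HMSBEAGLE and the other rows given here outside the named rule, DM1731_I-int:Copia:LTR at 3.11, TOM_I-int:Gypsy:LTR at 2.46, POGO:TcMar-Pogo:DNA at 1.90 and R2_DM:R2:LINE at 1.35, were chosen after their values were seen. All repeat rows together took 0.709%, 0.709% and 0.720% of the reads in the wild type libraries and 0.903%, 0.915% and 0.865% in the GCNA null libraries. The number of higher rows was 53 with all 6 libraries as separate samples (6 lower) and 48 with DESeq2 (4 lower), 17 to 19 without any 1 wild type library, and 11 without the sample of GCNA null replicates 1 and 2, where the median log2 difference was 0.06. The median was 0.39 without GCNA null replicate 3.

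**Figure D3:**
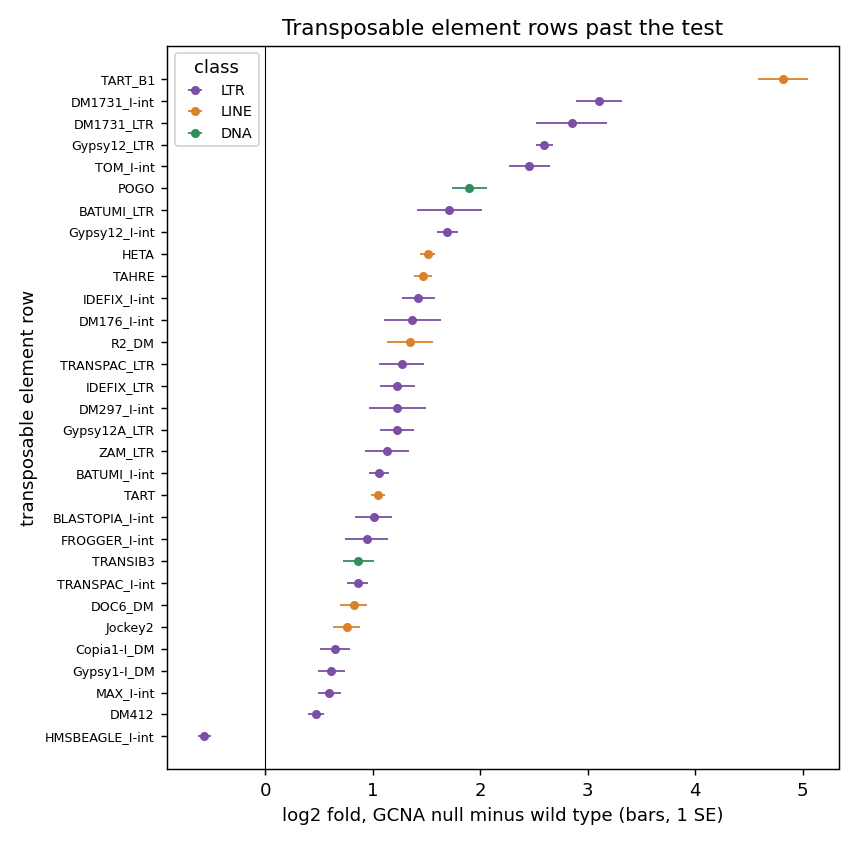
Log2 difference GCNA null minus wild type with its standard error for the 31 transposable element rows that passed the test, coloured by class (LTR, LINE or DNA). All but 1 lie above 0, up to 4.82 for TART_B1.

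Transcripts of the piRNA pathway, which silences transposable elements in the germline, moved in both directions. Of 33 members 3 were higher and 4 lower (4 and 5 adjusted over the list alone, 4 and 6 with 6 separate samples), and the median log2 difference was -0.011. The Tudor-domain gene qin fell from 5396 ± 371 to 3447 ± 45.2 (log2 difference -0.64, SE 0.07, limma adjusted p = 0.0054) and shu fell by 0.29 on the log2 scale, while BoYb and CG12721 (moon, which licenses transcription of piRNA clusters) rose by 0.45 and 0.57. CG12721 and qin overlap other annotated genes.

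Eggshell genes were measured at lower levels in part of the GCNA null libraries. Reads of 13 chorion and vitelline membrane genes took 2.94%, 3.19% and 2.93% of the wild type libraries, 1.29% and 1.24% of GCNA null replicates 1 and 2, and 2.99% of GCNA null replicate 3. Among 16 chorion genes none passed with limma on 5 or 6 samples, edgeR, limma-voom or DESeq2, over all rows or adjusted over the list alone, and none had an unadjusted p under 0.05. Their median log2 difference was -0.53 (camera adjusted p = 0.065, 0.017 with 6 separate samples, and 0.936 with an estimated correlation on 5 samples). Cp36 and Cp38 had log2 differences of -0.74 (SE 0.42) and -0.65 (SE 0.42). Among 16 vitelline membrane and yolk genes none passed with limma, edgeR or limma-voom on 5 samples, over all rows or adjusted over the list alone, whereas 4 were lower with 6 separate samples (8 adjusted over the list alone) and 1 with DESeq2, and 6 had an unadjusted p under 0.05. All 16 had a negative log2 difference (median -0.49), and camera placed the list lower than other rows (adjusted p = 0.0031, and 0.936 with an estimated correlation). The yolk protein genes Yp1 and Yp2 had log2 differences of -0.21 and -0.15. Without the sample of GCNA null replicates 1 and 2 the vitelline and yolk list did not pass (camera adjusted p = 0.196, median -0.11) and the chorion median was 0.13. Without GCNA null replicate 3 the chorion and vitelline and yolk medians were -1.22 and -0.92. In that setting 9 of 16 and 8 of 16 genes were called lower, but these calls set 1 GCNA null sample against 3 wild type samples, with the spread taken from the wild type alone.

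The other ovarian gene groups changed in a few members. Of 23 genes of follicle, escort and niche cells 1 rose, also adjusted over the list alone (peb, a transcription factor of follicle cells, log2 difference 0.35), and the median was 0.25 (camera adjusted p = 0.065, 0.032 with 6 separate samples, and 0.936 with an estimated correlation on 5 samples). The median was 0.11 without GCNA null replicates 1 and 2 and 0.14 with quantile normalization. With 6 separate samples 5 rose and 1 fell, and with DESeq2 3 and 1. Of 21 early germline genes 2 rose and none fell (4 and 2 adjusted over the list alone, 5 and 2 with 6 separate samples, 4 and 3 with DESeq2). These were blanks, which encodes a double-stranded RNA binding protein needed in spermatogenesis, from 26.8 ± 2.72 to 244 ± 83.7 (log2 difference 3.10, SE 0.28, limma adjusted p = 0.0024), and CG32364 (tut, a partner of Bam), with a log2 difference of 1.33. The median of this list was -0.051 while its mean was 0.21. Among 28 oocyte and axis genes pgc, which represses transcription in primordial germ cells, rose by 0.59 on the log2 scale, also adjusted over the list alone (1 higher and 2 lower with 6 separate samples and with DESeq2), and the median was -0.10 (-0.060 without GCNA null replicates 1 and 2, and -0.047 with quantile normalization). Of 20 apoptosis and autophagy genes Atg8a rose by 0.63 and Dredd fell by 0.52 on the log2 scale (3 higher and 1 lower adjusted over the list alone, 4 and 2 with 6 separate samples and with DESeq2, median 0.09). Of 20 ecdysone genes Eip75B rose by 0.75 (1 higher and 1 lower adjusted over the list alone, 2 and 2 with 6 separate samples, 1 and 2 with DESeq2, median -0.00039).

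Of 21 heat shock genes 3 rose and 1 fell (6 and 1 adjusted over the list alone, 7 and 1 with 6 separate samples, 6 and 2 with DESeq2, median 0.11, and 0.18 with quantile normalization). Hsp70Ab rose from 5491 ± 1313 to 12102 ± 609 normalized counts (log2 difference 1.17, SE 0.20, limma adjusted p = 0.023), Hsp70Bbb and the co-chaperone gene stv had log2 differences of 1.02 and 0.99, and Hsp26 fell by 0.52 on the log2 scale. The Hsp70 copies are nearly identical, so how their reads were divided is uncertain. Of 35 genes of xenobiotic metabolism 6 rose and 1 fell (7 and 2 adjusted over the list alone and with 6 separate samples, median 0.42, and 0.12 with quantile normalization), and camera placed the list higher than other rows (adjusted p = 0.028, and 0.936 with an estimated correlation). The glutathione transferase gene GstD3 rose from 1088 ± 175 to 3424 ± 94.1 (log2 difference 1.67, SE 0.14, limma adjusted p = 0.0018) and GstE7 had a log2 difference of 0.68, whereas its neighbour GstE6 fell from 8678 ± 1155 to 4927 ± 646 (log2 difference -0.81, SE 0.13, limma adjusted p = 0.018). The camera call was lost without a filter on low values (0.057), with a mean of at least 50 (0.122), with quantile normalization (0.122) and without GCNA null replicate 3 (0.055). Of 19 immune genes Rel and IM4 rose (log2 differences 0.35 and 1.41), also adjusted over the list alone (2 higher and 1 lower with 6 separate samples, 3 and 2 with DESeq2), and the list's median of -0.23 and mean of -0.10 differed in sign from its camera direction (adjusted p = 0.805). The immune median was -0.0046 without GCNA null replicates 1 and 2 and -0.58 with quantile normalization.

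Of 90 cytosolic ribosomal protein genes 3 rose and 1 fell, also adjusted over the list alone, with a median log2 difference of 0.016. The 3 that rose are scarce paralogs with known testis expression: RpL22-like, RpS10a, which rose from 18.7 ± 2.49 to 421 ± 39.6 normalized counts (log2 difference 4.43, SE 0.22, limma adjusted p = 0.0004), and RpL37b, with a read ratio of 16.2 (95% interval 5.26 to 81.3, counting error only) over 3 wild type reads. The abundant sta, which encodes the laminin receptor homologue of the small subunit, fell from 110148 ± 19178 to 62554 ± 1278 (log2 difference -0.80, SE 0.16, limma adjusted p = 0.039). It lies 379 kb from Gcna. Of 73 mitochondrial ribosomal protein genes 2 fell, also adjusted over the list alone (mRpL14 by 0.75 and mRpS31 by 0.38 on the log2 scale), 58 had a negative log2 difference (median -0.12), and camera placed the list lower than other rows (adjusted p = 5.3e-05, and 0.936 with an estimated correlation). This call passed under all 18 other settings in which camera was run with the preset correlation. The count of members was less stable: 14 fell and 1 rose with 6 separate samples, and 7 and 1 with DESeq2.

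Small and long non-coding RNAs changed in both directions. Of 226 snoRNA rows 7 rose and 2 fell (6 and 1 adjusted over the list alone, 14 and 9 with 6 separate samples, 13 and 4 with DESeq2, median -0.10), among them snoRNA:CG32479-a, snoRNA:Psi18S-1347b and snoRNA:Psi28S-1192a with log2 differences of 1.36, 1.74 and 0.42. Of 25 snRNA rows 3 rose and 2 fell (4 and 5 adjusted over the list alone and with 6 separate samples, 5 and 4 with DESeq2). The 3 that rose were the U1 copies snRNA:U1:95Ca, snRNA:U1:95Cb and snRNA:U1:95Cc, at 0.38, 0.37 and 0.58, and snRNA:U2:34ABc fell by 0.50 on the log2 scale. These copies are nearly identical. Of 334 long non-coding RNA rows 17 rose and 11 fell (20 and 13 adjusted over the list alone, 41 and 24 with 6 separate samples, 28 and 20 with DESeq2), with CR43967 at a log2 difference of 3.83. The snRNA and long non-coding medians were 0.12 and 0.11, that of snRNAs was -0.066 without GCNA null replicate 3, and that of long non-coding RNAs was 0.063 without replicates 1 and 2. None of 27 microRNA precursor rows or 8 scaRNA rows passed with limma, edgeR, limma-voom or DESeq2 on 5 samples, over all rows or adjusted over the list alone, with 2 and 1 rows at an unadjusted p under 0.05. With 6 separate samples 1 microRNA precursor row was lower and still no scaRNA row passed. The most abundant of them, mir-4956 and mir-4917, had log2 differences of 0.08 and -0.36, and scaRNA:MeU5-C46 and scaRNA:PsiU1-6 had 0.36 and 0.31. The medians of these lists were -0.00044 and 0.30, and that of scaRNAs was 0.16 without GCNA null replicate 3. None of the 5 ribosomal RNA rows passed with limma, edgeR or limma-voom on 5 samples, also adjusted over the list alone, 1 was higher with DESeq2 and with 6 separate samples, and 1 had an unadjusted p under 0.05; the 5 had a median of 0.40. The 2 largest, CR41602 and CR41609, had log2 differences of 0.58 and 0.68. The medians of these non-coding classes moved with the scaling: under quantile normalization they were -0.37 for snoRNAs, -0.11 for snRNAs, -0.15 for long non-coding RNAs, -0.37 for microRNA precursors, 0.013 for scaRNAs and 0 for ribosomal RNA. Ribosomal RNA rows took 3.26%, 6.49% and 3.70% of the wild type reads and 6.73%, 6.77% and 6.23% of the GCNA null reads.

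Markers of other tissues were counted in the same way, and the GCNA null libraries stood apart from one another on several of these lists. None of 19 muscle markers passed with limma, edgeR or limma-voom on 5 samples, over all rows or adjusted over the list alone, 1 was higher with DESeq2 and 2 with 6 separate samples, and 3 had an unadjusted p under 0.05 (Tm1 at -0.13 and Act57B at -0.26, list median -0.11). The muscle median was 0.25 without GCNA null replicate 3 and -0.43 without replicates 1 and 2. Muscle markers took 0.239%, 0.237% and 0.146% of the reads of GCNA null replicates 1 to 3 and 0.159% to 0.210% in the wild type. None of 7 nervous system markers passed with limma on 5 or 6 samples, edgeR, limma-voom or DESeq2, also adjusted over the list alone, and none had an unadjusted p under 0.05 (unc-13 at -0.07 and elav at 0.36, list median 0.022, 0.15 without GCNA null replicate 3, -0.22 without replicates 1 and 2 and -0.14 with quantile normalization). None of 18 gut markers passed with limma or edgeR on 5 samples, also adjusted over the list alone, 1 was higher with DESeq2, with limma-voom and with 6 separate samples, and 1 had an unadjusted p under 0.05 (Jon25Biii at 1.47 with SE 1.12, Jon65Aiv at -0.92 with SE 1.32, list median -0.31). The direction of the gut median depended on the GCNA null library kept, at 0.56 without replicate 3 and -0.90 without replicates 1 and 2, and it was -0.54 with quantile normalization. Gut markers took 0.0458% of the reads of wild type replicate 2 and 0.00184% to 0.0101% elsewhere. Of 13 fat body markers 3 rose, also adjusted over the list alone (Lip4, Lsd-1 and Ilp6, with log2 differences of 1.38, 1.22 and 1.47), while the list's median was -0.27 and its mean 0.10. The fat body median was -0.40 without GCNA null replicate 3 and 0.44 without replicates 1 and 2, and the list took 0.0152%, 0.0155% and 0.0316% of the reads of GCNA null replicates 1 to 3 and 0.0188% to 0.0265% in the wild type. Of 13 hemocyte markers the prophenoloxidase genes PPO1 and PPO2 rose by 2.17 and 2.16 on the log2 scale, also adjusted over the list alone (3 higher with 6 separate samples and with DESeq2, median 0.35). The hemocyte camera adjusted p was 0.065, 0.048 with 6 separate samples, and 0.936 with an estimated correlation on 5 samples. The hemocyte median was 0.71 without GCNA null replicate 3, 0.15 without replicates 1 and 2 and 0.20 with quantile normalization. Of 8 oviduct, spermatheca and uterus markers Spn77Bc, with a log2 difference of 2.26, and the octopamine receptor gene Oamb, with 1.31, rose, also adjusted over the list alone (median 2.13, camera adjusted p = 0.071). Of 5 testis markers that could be tested 1 rose and 1 fell (1 and 2 adjusted over the list alone): aly, a regulator of meiotic entry in spermatocytes, went from 1.95 ± 1.88 to 60.2 ± 28.8 (log2 difference 4.56, SE 0.75, limma adjusted p = 0.021) and topi, which acts in the same pathway, from 77.8 ± 8.84 to 21.4 ± 8.20 (log2 difference -1.86, SE 0.30, limma adjusted p = 0.021). The median of the 5 was -0.023 and their mean 0.52. No row was listed as mitochondrially encoded or as a tRNA.

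Around the targeted gene, changed genes were more frequent. Within 1 Mb of Gcna 20 of 204 tested genes (9.80%) had changed, 8 higher and 12 lower, against 583 of 9590 (6.08%) elsewhere (odds ratio 1.68, two-sided Fisher's exact p = 0.038). Within 3 Mb it was 41 of 359 (11.4%, odds ratio 2.04, two-sided Fisher's exact p = 0.00012). Over the whole X chromosome 5.54% of genes had changed, against 6.29% on the autosomes (two-sided Fisher's exact p = 0.27). On the X chromosome beyond 3 Mb of Gcna the share was lower than on the autosomes, 53 of 1337 genes (3.96%, odds ratio 0.615, two-sided Fisher's exact p = 0.00059). In the window CG2694 fell from 5178 ± 180 to 1653 ± 81.8 (log2 difference -1.65, SE 0.06, limma adjusted p = 0.00012). CG3857, CG2712 and CG11382 had log2 differences of -1.38, -1.20 and -1.20, and Tsp3A and Atf3, a stress-responsive transcription factor, had 1.00 and 1.33. Of the genes given above, sta, Ilp6, mRpL14 and CG3690 also lie within 1 Mb of Gcna, at 379, 466, 478 and 910 kb. CR40469, Dredd, CG32783, CR43614 and peb, also given above, lie within 3 Mb, at 1739, 1226, 2079, 2503 and 2752 kb. The changes of all these genes cannot be told apart from differences linked to this region. The share within 1 Mb no longer passed Fisher's exact test without any 1 of the wild type libraries (5.39%, 4.41% and 3.92%), without GCNA null replicate 1 or 2 (9.31% and 8.82%) and in 6 further settings.

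**Figure D4:**
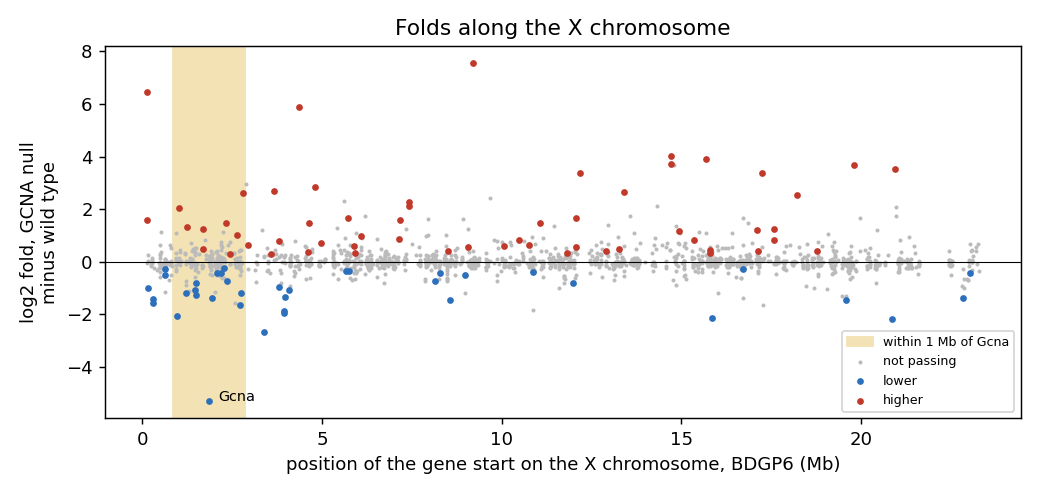
Log2 difference GCNA null minus wild type of each tested gene along the X chromosome (position in Mb, x axis), with changed genes coloured; the band marks 1 Mb on either side of Gcna. In the band 8 changed genes lie above 0 and 12 below, Gcna itself not counted.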

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

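The fit with 6 separate samples was the one planned; merging GCNA null replicates 1 and 2, and leaving both out, were chosen after the data were seen. No changed row reversed its direction under any setting. Gcna stayed far past the threshold throughout, and the counts under other pseudocounts, filters, TMM scaling, robust empirical Bayes, edgeR and limma-voom stayed within 1.5 times. Higher rows numbered 431, 755 with DESeq2, 935 with 6 separate samples, and 94 to 426 with libraries left out. Lower rows numbered 214, 542 with DESeq2, 749 with 6 separate samples, and 52 to 277 with libraries left out. Rows changed at least 2-fold numbered 320, 497 with 6 separate samples, and 121 to 342 with libraries left out. Higher transposable element rows numbered 30, 48 with DESeq2, 53 with 6 separate samples, and 11 to 30 with libraries left out. Gene lists past camera numbered 4, 0 with an estimated correlation, 0 with fry, 10 with quantile normalization, 8 with 6 separate samples, and 4 to 8 with libraries left out; camera was not run on DESeq2. The share of changed genes within 1 Mb of Gcna was 9.80% and lost its Fisher's exact call without a filter (7.08%), with TMM or edgeR (9.31% in both), with DESeq2 (15.2%), with 6 separate samples (20.6%) and within 0.5 Mb (9.09%), and it was 3.92% to 9.31% with libraries left out. Leaving out libraries leaves fewer samples, and without GCNA null replicate 3, or 1 and 2, a lone one assumed to vary like the wild type; the other causes were not tested. Of 645 changed rows, 357 were shared with the fit without GCNA null replicate 3 and 142 with the fit without replicates 1 and 2. Among the 18 named rows that did not pass, 11 changed sign under some setting. Depth limits rows under 1000 reads, where counting was a sizeable part of the spread.

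The replicate numbers gave no sign of pairing: the deviations of same-numbered libraries correlated at -0.18, 0.07 and -0.09. GCNA null replicates 1 and 2 were too alike for this check to settle it. With wild type replicate 1 they correlated at -0.18 and -0.17. With 6 separate samples, a replicate block gave 640 higher and 477 lower rows, 40 higher transposable element rows, 5 lists past camera and a share near Gcna of 15.7%.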

Other observations

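The test of the shift of the transposable element median was chosen after its value was seen; the genes named here outside the report were chosen after their values were seen.

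Further large increases lay outside the fixed lists, some of them in genes of cilia and sperm tails. Dhc98D, an axonemal dynein heavy chain gene, rose from 117 ± 31.1 to 1755 ± 307 normalized counts (log2 difference 3.92, SE 0.24, limma adjusted p = 0.00066). Oseg5, which acts in intraflagellar transport, rose from 21.4 ± 11.3 to 276 ± 40.9 (log2 difference 3.79, SE 0.52, limma adjusted p = 0.012). CG31125 rose from 36.1 ± 2.16 to 862 ± 50.9 (log2 difference 4.54, SE 0.16, limma adjusted p = 0.00012), and the X-linked gene hog had a log2 difference of 4.04 (SE 0.31, limma adjusted p = 0.0014). Whether genes of cilia or sperm are enriched among the changed rows was not tested.

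Single RNAs known from testis rose (RpL22-like, RpS10a, RpL37b, blanks and aly), but the fixed testis list did not move one way: of 5 members tested 1 rose and 1 fell, with a median log2 difference of -0.023. Testis or sperm RNA in the GCNA null libraries is a candidate source of the single increases. Of 12 abundant late spermatogenesis transcripts, 3 had a row in the table, with 14 reads in wild type and 20 in GCNA null libraries (ratio of normalized counts 1.41, read ratio 1.34, 95% interval 0.643 to 2.86). The ratio lies under 1.5, but its interval does not, and the other 9 of the 12 transcripts had no row in the table. All 13216 rows of the table held reads. A missing row may thus stand for a transcript without reads, or for one that the annotation used did not name. On these rows this source cannot be told apart from expression in the ovary. That topi fell while aly rose goes against a uniform addition of testis RNA, from single genes only. Expression in Gcna-deficient germ cells stays open and untested.

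Differences between the chromosomes of the 2 stocks are a candidate explanation for part of the changed genes. If the chromosome around the null allele kept its founder's sequence, changed genes would be denser near Gcna. The odds ratio within 1 Mb was 1.68 (two-sided Fisher's exact p = 0.038), as this explanation needs. The call was lost without any 1 wild type library, with 6 separate samples, DESeq2, edgeR or TMM, and within 0.5 Mb. The share did not rise towards Gcna: it was 9.09% within 0.5 Mb, 9.80% within 1 Mb and 11.4% within 3 Mb. These windows are nested, and a kept stretch that spans them all needs no such rise. Their shares thus cannot weigh against this explanation. On the X chromosome beyond 3 Mb of Gcna the share was 3.96%, against 6.29% on the autosomes. Outside the 1 Mb window 48 pairs of neighbouring, non-overlapping genes were both changed, against a median of 27 (95% range 18 to 37) in 10000 shuffles within chromosome arms (one-sided permutation p = 0.0001, the smallest these shuffles can give). Stretches of founder chromosome may do this, but so may neighbours that are regulated together, and near-identical neighbours that share reads. These stay open. Genes between 1 and 3 Mb from Gcna, where changed genes were also more frequent, stayed in this count. The p-value thus does not speak for the rest of the genome alone. On 3R p24-2 had no wild type read, as a segment missing from the wild type stock might show. Unc-115b rose from 84.9 ± 7.83 to 646 ± 85.7, and CG18542 and CG32939, which share identical reads, had a log2 difference of 0.84 (SE 0.12). CG18542 and CG32939 thus count as 1 measurement. All 3 genes had reads in the wild type, which a missing segment that spans them would not by itself leave. A segment missing at p24-2 alone stays open. No genome sequence of the stocks was used here.

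Other values on the X chromosome and on 2R are given without an explanation. The neighbouring, near-identical genes HIP-R and HIP had log2 differences of -0.97 and 0.77, from 8063 ± 328 to 4119 ± 78.5 and from 5895 ± 184 to 10068 ± 583 normalized counts. w, the gene whose mutation gives wBerlin its white eyes, lies within 1 Mb of Gcna at 2790599 to 2796466 and rose from 30.2 ± 6.40 to 196 ± 74.9 (log2 difference 2.63, limma adjusted p = 0.0086). Whether the null allele carries an eye colour marker is not given in the sources used here, so the w reads cannot be assigned to the gene or to a construct. In a stretch of 2R 4 changed genes were all higher: RpL22-like (log2 difference 5.88), CG12782 (4.86), CG13540 (4.95) and ord (2.26), all between 23246610 and 23275536.

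The higher transposable element rows were set against 2 explanations. Scaling between libraries would make the count of higher rows fall below 0.5 of its 30 with another scaling; it was 23 with quantile normalization and 30 with TMM, which goes against scaling as the whole cause of these calls. The median over all 195 rows is another matter: it was 0.22, 0.22 with TMM and 0.079 with quantile normalization, so how far scaling accounts for the list-wide shift stays open. If lower piRNA pathway transcripts were the cause, the median log2 difference of that list was to lie below -0.3, and if not, above -0.1. It was -0.011 (95% bootstrap interval over the 33 genes -0.13 to 0.05). The interval covers the spread between genes and not that between samples, so it cannot exclude a fall of the whole list. The list's median was -0.033 without GCNA null replicates 1 and 2 and -0.016 without replicate 3. These medians do not exclude the explanation, because 4 of 33 members, qin among them, were lower, and the loss of 1 member may be enough to release elements. A different set of element copies in the stocks, and an effect of Gcna itself, remain open and cannot be told apart by these libraries.

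The 5 samples can be split into 2 and 3 in 10 ways, too few for a share under 0.05. The real split gave 645 changed rows and the highest of the others 7.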
